A study of Homo sapiens with 32 samples.

How the data were processed

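Total RNA from human whole blood was sequenced in 32 libraries, taken 24 h after sham irradiation or after 3 Gy given at 1 of 3 dose rates. Per the labels, blood was collected, irradiated with a Clinac, frozen, thawed and extracted with a PAXgene kit. The RNA was cleared of globin transcripts and depleted of ribosomal RNA before stranded libraries were made. The 4 groups hold 8 libraries each and are named as the labels name them: CTL (sham, 0 Gy), REF (1 Gy/min), VHDR (600 Gy/s) and FLASH. The FLASH rate is printed in the labels with a run-together exponent and was read as 300000 Gy/s. The labels tie no library to a donor, batch or date, so libraries were numbered within groups only to name them. P-values measure the spread between these libraries, which may be technical or may lie between donors.

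The deposited table holds 57163 gene symbols by 32 libraries, of which 92.4% match a symbol of GENCODE release 29. Per the submitters' processing notes, the authors used bcl2fastq 2.19, kallisto 0.44.0, sleuth and DESeq2, the last 2 without versions. Those notes name GRCm38, a mouse assembly, although the table's symbols are human; no coordinates are therefore printed. The deposited values are a signal, namely gene-level estimated counts scaled by 1 factor per library: the median ratio of each library to the geometric mean over libraries was 1.01128 in all 32, over the 13718 genes above 0 everywhere. The value of 1 read differed between libraries, from 0.230 to 5.23. Whole reads could not be recovered: of the values under 10 estimated reads, 49.8% to 69.9% per library lay within 0.1 of a whole number. The plan, written before the data were examined, set a count model for counts and limma for normalized values. The second applied, and count models were not run.

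Genes with a mean of at least 1 over the 32 libraries were tested, 24796 in all. The values were taken as log2(value + 1) and fitted in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with 4 group means and an intensity trend in 1 fit over all 32 libraries. The fit gave 7 contrasts: each dose rate against sham, the mean of the 3 dose rates against sham (called irradiated), and each pair of dose rates. A moderated F test asked for any difference among the 3 rates. P-values were adjusted by Benjamini-Hochberg within each contrast, with calls at 0.05. Group values are means ± SD of the normalised values with n = 8, and fold changes are log2 ± SE.

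A set of 22 gene lists was fixed before the data were examined, from general knowledge of radiation responses and blood cells; no list was taken from these libraries. Each list with at least 5 tested genes was tested in the 7 contrasts with camera at a preset inter-gene correlation of 0.01, adjusted over all 154 tests. The tests were repeated with the correlation estimated from the data, and with fry, which asks only whether a list's genes move on balance 1 way. A score per library was the mean over the p53 target genes, or over the B cell markers, of the log2 value minus the gene's mean. Scores, ribosomal RNA shares and depths were compared for the 6 pairs of groups by 2-sided exact permutation tests, adjusted over the 6, with 95% intervals from inverting the test. Lists of TGF-beta response genes and sterol synthesis genes were added after fold changes of other genes had been seen.

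Genes to name were set by a rule written before the data were examined. It took 18 focal genes, and the 10 largest rises and 10 largest falls in irradiated against sham with an average log2 of at least 1 and the same direction at every dose rate. It also took up to 3 called members of each list, and up to 5 rises and 5 falls with the smallest adjusted p for each pair of dose rates. Sex-linked marker genes, receptor segments and clone names were left out. A few members of lists are named outside the rule and were chosen after their values were seen. They are list members neither focal nor among the largest changes, such as BTG2, FOSL1, HSPH1 and the H1 histones.

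Depth was estimated from the most common value among the low positive values of each library, taken as 1 read, since the table gives no read counts. Outside ribosomal RNA it ran from 1.27 to 27.2 M (mega) reads per library, a 21.5-fold range, so the same value rests on different numbers of reads. Ribosomal RNA was taken as 5 annotated genes, 3 of which hold identical values in all 32 libraries. Because its share differed between groups, fits were added with that share as a covariate, with a mean of at least 50 (10246 genes; near 9.56 reads in the shallowest library), and within the libraries over and under 50% ribosomal RNA where both groups had at least 3. These were chosen after the shares were seen.

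The procedure was tested on simulated data made from each gene's mean, its spread within groups and each library's value of 1 read, with 200 genes changed. At a true 2-fold change in REF against sham it recovered 43.3% of changed genes, and 92.6% of those with a mean of at least 50. For FLASH against sham the shares were 34.3% and 81.5%, and for FLASH against REF 35.8% and 85.2%. Of the calls, 8.43%, 4.41% and 5.56% were false in these contrasts, and 10.9% in irradiated against sham. FLASH against VHDR, simulated after the results were seen, gave 31.3% and 70.4%. With nothing changed, each contrast gave 0 or 1 call by limma, and the median of genes with a mean under 50 moved by up to 0.16 on the log2 scale, in FLASH against sham. The simulated libraries were drawn independently, with no shift that follows the ribosomal RNA share and no likeness between libraries. The false shares may therefore be too low for the real data.

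Other settings were voom with sample quality weights on approximate reads, scaling to the total of all genes or to the total without globin, mitochondrial and ribosomal RNA genes, no filter, at least 1 per M of the summed values in 8 libraries, a pseudocount of 0.1, and only the groups compared. Splits of the libraries into groups of the same sizes were drawn 100 times per contrast. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 made the library table and the figures.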

Results

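Gene expression in human whole blood was measured by total RNA sequencing 24 h after a single dose of 3 Gy delivered at conventional or very high dose rates, with sham-irradiated blood as the control. The series title names a blood gene signature for reconstructing radiation dose and asks how dose rate affects it. Sham blood (CTL), blood irradiated at 1 Gy/min (REF), at 600 Gy/s (VHDR) and at 300000 Gy/s (FLASH, ultra-high dose rate delivery) each gave 8 libraries.

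The libraries differed in the ribosomal RNA left after depletion and in depth. Ribosomal RNA took 71.6% ± 11.4 (SD, n = 8) of the summed values in sham, 38.3% ± 42.9 in REF, 53.8% ± 35.3 in VHDR and 17.8% ± 18.4 in FLASH. It took over 50% in 8 of 8 sham, 3 of 8 REF, 5 of 8 VHDR and 1 of 8 FLASH libraries. The share was lower in FLASH than in sham by an exact permutation test, with a difference of -53.7 points (adjusted p = 0.00280), and the other 5 pairs gave adjusted p from 0.0816 upward. Estimated reads with ribosomal RNA included averaged 11.1 M ± 1.70 (M, mega) in sham, 18.5 ± 5.00 in REF, 13.2 ± 5.06 in VHDR and 19.1 ± 5.89 in FLASH. Those outside ribosomal RNA averaged 3.12 M ± 1.37 in sham, 13.2 ± 10.5 in REF, 7.54 ± 7.93 in VHDR and 16.4 ± 7.49 in FLASH. Only FLASH against sham differed in depth by the exact permutation test, by 13.3 M reads (adjusted p = 0.00186; the other pairs 0.0779 or higher). All 8 sham libraries lay over 50% ribosomal RNA, so FLASH could be set against sham only across that divide. Directions below are relative to the deposited library scaling. Scaling to the total of all genes, most of which is ribosomal RNA in sham, took the median log2 fold change of all genes from 0.02 to 0.84 for irradiated against sham and from -0.06 to -0.37 for VHDR against REF.

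**Figure D1:**
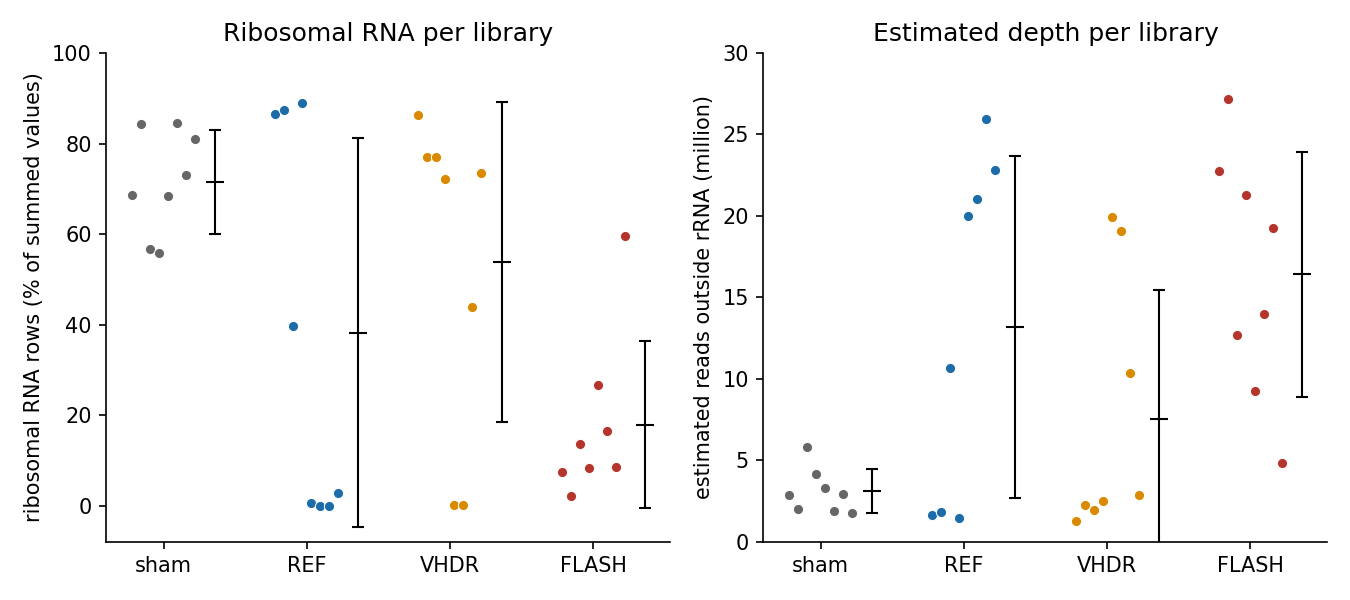
Ribosomal RNA as a percent of summed values (left) and estimated reads outside ribosomal RNA in M (right), 1 point per library, with the mean and SD beside each group of 8. Sham libraries lie between 55.7% and 84.6% ribosomal RNA, while REF spans 0.033% to 88.8%.

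The first question was which genes respond to 3 Gy whatever the dose rate. FDXR, a mitochondrial ferredoxin reductase that p53 induces, had a mean normalised value of 37.1 ± 13.6 (SD, n = 8) in sham and rose to 378 ± 46.0 in REF, 242 ± 28.9 in VHDR and 266 ± 42.3 in FLASH. DDB2, a damage-recognition factor of nucleotide excision repair, rose by a log2 fold change of 2.51 ± 0.11 over the 3 rates (adjusted p = 5.5e-19), and AEN, an apoptosis-enhancing nuclease, by 3.19 ± 0.13 (adjusted p = 3.32e-19). PHLDA3, an inhibitor of AKT signalling, and EDA2R, a receptor of the TNF receptor family, rose from near 0 (1.48 ± 3.05 and 2.71 ± 2.61 in sham), by 4.65 ± 0.37 and 4.39 ± 0.31. In the other direction the immediate early transcription factors EGR2 (-3.35 ± 0.27), NR4A1 (-2.26 ± 0.22), EGR1 (-2.12 ± 0.20) and FOS (-2.04 ± 0.23) fell. The contrast averages the rates, and for those 4 genes REF alone against sham gave -0.26 ± 0.34, -0.66 ± 0.26, -0.58 ± 0.24 and -0.52 ± 0.28, none of them called by this unpaired fit.

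Across the 24796 tested genes, 439 rose and 214 fell in the 24 irradiated libraries against the 8 sham libraries. The balance depended on the method: rises were 67.2% of these calls, but 41.1% by voom, 53.9% with ribosomal RNA as a covariate and 99.4% with scaling to the total of all genes. Of the 61 p53 target genes, 38 rose, 1 fell and 22 were not called (41 and 1 adjusted over the list alone; camera adjusted p = 9.88e-68, and 3.06e-12 with an estimated correlation). The member that fell was BTG2 (-1.39 ± 0.17), an antiproliferative gene that is also on the immediate early list. In all 24 irradiated libraries, FDXR, DDB2, AEN, PCNA, BAX, BBC3, XPC, RPS27L, PHPT1, ASCC3, GADD45A and TNFRSF10B lay above every sham library. Among these, PCNA, the DNA polymerase clamp, rose by 2.07 ± 0.09, the apoptosis genes BAX and BBC3 by 1.79 ± 0.10 and 1.75 ± 0.13, RPS27L by 2.07 ± 0.10 and the repair factor XPC by 1.49 ± 0.08. PHPT1 rose by 1.79 ± 0.11, ASCC3 by 1.65 ± 0.11, GADD45A by 1.46 ± 0.13 and the death receptor gene TNFRSF10B by 1.21 ± 0.12. CDKN1A, the cell cycle inhibitor p21, rose by 1.48 ± 0.15, with 22 of 24 libraries above every sham one. MDM2, the ubiquitin ligase that degrades p53, rose by 1.06 ± 0.08 (23 of 24) and SESN1 by 1.11 ± 0.12 (22 of 24).

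**Figure D2:**
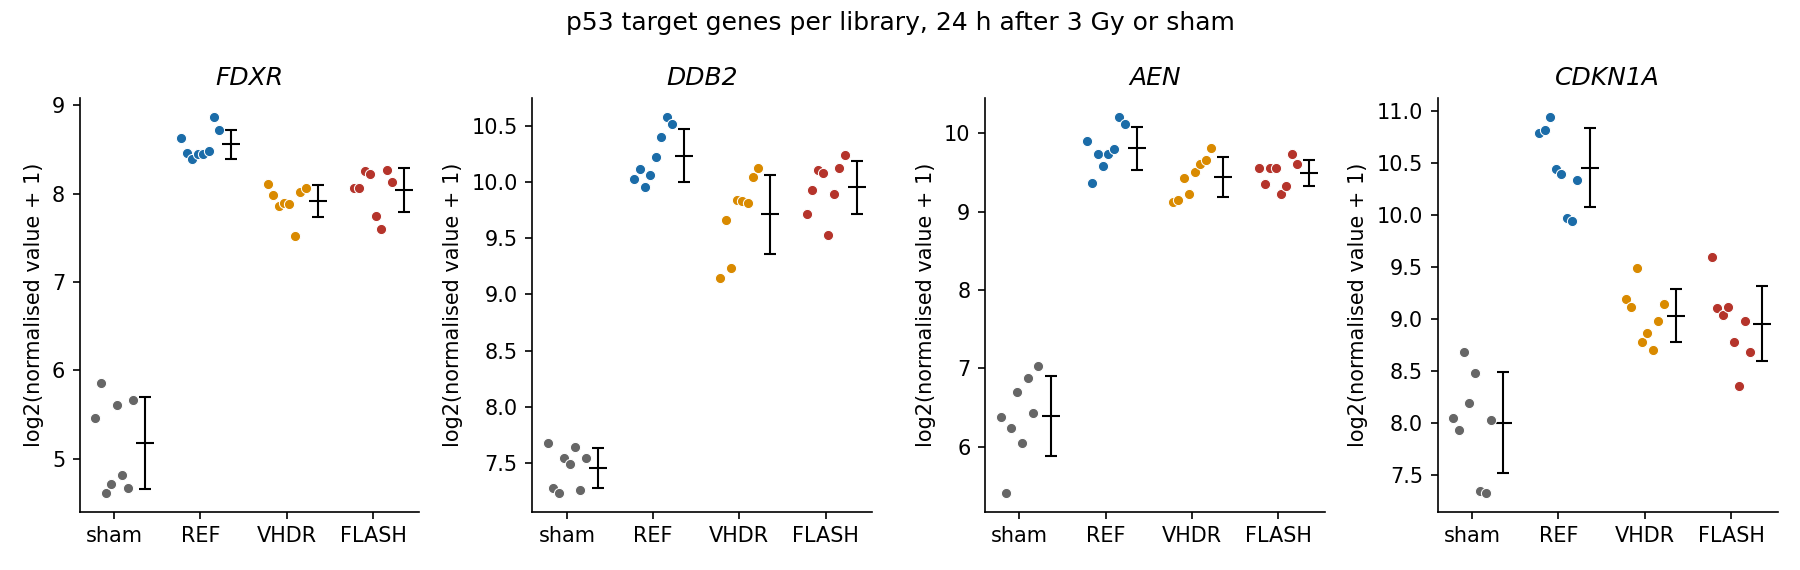
Normalised values of FDXR, DDB2, AEN and CDKN1A on a log2 scale, 1 point per library, with the mean and SD beside each group of 8. FDXR lies between 4.61 and 5.86 in sham and at or above 7.52 in the irradiated groups.

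Other large rises were MIR34AHG, the host transcript of the p53-induced microRNA miR-34a (3.56 ± 0.29), and the cytidine deaminase gene APOBEC3H (3.05 ± 0.27), both above every sham library in 24 of 24. LNCTAM34A, which lies next to MIR34AHG, is listed at 0 in every sham library and averaged 7.70 ± 5.18 in REF, 6.35 ± 6.59 in VHDR and 5.18 ± 2.61 in FLASH. Reads shared between these neighbours cannot be separated here. CARD10 (2.76 ± 0.42) rose at the high rates, where it lay above every sham library in 8 of 8 VHDR and 8 of 8 FLASH libraries, while REF gave 0.22 ± 0.52. SMIM11A (2.63 ± 0.58) shares sequence with a near-identical gene copy, and its call ended with ribosomal RNA as a covariate (adjusted p = 0.0911). The remaining large falls were PTGS2, which encodes cyclooxygenase 2 (-2.34 ± 0.32), the cytokine gene OSM (-1.89 ± 0.16), MIR210HG (-2.30 ± 0.64), LRRC32 (-1.80 ± 0.49), the small nuclear RNA copy RNU2-6P (-2.04 ± 0.36) and the readthrough transcript ATP6V1G2-DDX39B (-2.18 ± 0.49). The last 2 carry sequence shared with other genes, and the calls of MIR210HG and LRRC32 ended without a low-value filter (adjusted p = 0.104 and 0.0760).

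The other lists were read in the same contrast, irradiated against sham, which averages the dose rates. A gene called in it need not have moved in REF, where 77 genes rose and 2 fell against sham. Of 35 blood dose marker genes, 30 rose and 1, the lymphocyte receptor gene LY9 (-0.46 ± 0.13), fell, with 30 and 1 adjusted over the list alone (camera adjusted p = 3.93e-99, and 8.92e-11 with an estimated correlation). Of these genes, 19 are also on the p53 list, which shares 4 genes with the DNA repair list as well. Of 57 DNA repair genes, 6 rose and none fell by limma: DDB2, PCNA, XPC, the translesion polymerase gene POLH (1.65 ± 0.17), the ligase gene LIG1 (1.17 ± 0.11) and PALB2 (0.82 ± 0.14). Adjusted over the list alone the counts were 6 and 1, the list median was -0.02 although the mean was 0.10, and camera did not call it (adjusted p = 0.170). Of 76 cytosolic ribosomal protein genes only RPS19 was called (1.01 ± 0.12; also 1 over the list alone). Camera called the list (adjusted p = 0.00185), but not with an estimated correlation (adjusted p = 0.904). No gene of the 42 cell cycle and proliferation genes was called by limma in any of the 7 contrasts, nor adjusted over the list alone (camera adjusted p = 0.338).

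Immediate early genes, the first to be transcribed when cells are stimulated, had the most falls of any list among calls over all genes. Of 24 tested, 15 fell and 1, FOSL1 (1.45 ± 0.34), rose in irradiated against sham (16 and 1 adjusted over the list alone; camera adjusted p = 9.79e-29, and 0.00122 with an estimated correlation). Among 30 hypoxia response genes, 8 fell (9 over the list alone), including HK2, a hexokinase of glycolysis (-1.48 ± 0.26), MXI1 (-0.99 ± 0.14) and DDIT4, an inhibitor of mTOR signalling (-0.64 ± 0.11). The call of the list was lost with an estimated correlation (adjusted p = 0.206). Its median against sham was -0.17 in REF, -0.57 in VHDR and -0.42 in FLASH. With ribosomal RNA as a covariate, 0 members were called in REF, while 10 fell in VHDR and 9 in FLASH. Of 38 NF-kB and inflammatory genes, OSM, PTGS2, the neutrophil chemokine gene CXCL8 (-1.31 ± 0.29) and G0S2 (-1.18 ± 0.29) fell (1 rose and 4 fell over the list alone; camera adjusted p = 0.0546). The 32 NRF2 oxidative stress genes had 1 rise, the haem oxygenase gene HMOX1 (0.45 ± 0.12), and 1 fall, the transketolase gene TKT (-0.52 ± 0.15). Over the list alone 2 rose and 1 fell (camera adjusted p = 0.999). HERPUD1 fell (-0.37 ± 0.07), alone among 28 heat shock and unfolded protein genes, and 1 fell over the list alone (camera adjusted p = 0.218).

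Few markers of blood cell types were called. The B cell marker genes MS4A1 (0.02 ± 0.32), CD79A (-0.68 ± 0.35) and FCER2 (0.69 ± 0.46) were not called, and neither was any of the 39 tested B cell markers by limma, by the list alone or with all genes. Camera called that list lower (adjusted p = 0.00683; 0.871 with an estimated correlation). The B cell score differed from sham by -0.31 in REF (95% interval -0.96 to 0.33), -0.14 in VHDR (-0.74 to 0.46) and -0.28 in FLASH (-0.90 to 0.33), with adjusted p of at least 0.739 by exact permutation, so shifts within those intervals were not excluded by this unpaired test. Of 33 T cell markers, CD28, a costimulatory receptor, fell (-0.69 ± 0.16), with 1 rise and 1 fall over the list alone (camera adjusted p = 0.0203; 0.871 with an estimated correlation). Of 31 NK and cytotoxic cell markers, the chemokine gene XCL1 (-1.38 ± 0.38), the fractalkine receptor gene CX3CR1 (-1.15 ± 0.33) and NCAM1 (-1.01 ± 0.29) fell, with 4 falls over the list alone (camera adjusted p = 0.000196; 0.688 with an estimated correlation). With ribosomal RNA as a covariate the NK list median went from -0.35 to -0.09 and no member was called by limma. For XCL1, CX3CR1 and NCAM1 the adjusted p became 0.0733, 0.244 and 0.314. Of 32 monocyte and macrophage markers, the formyl peptide receptor gene FPR3 (0.62 ± 0.16) and the cathepsin gene CTSL (1.03 ± 0.28) rose (3 over the list alone; camera adjusted p = 0.805). Of 34 neutrophil markers, VNN3 (-0.86 ± 0.23) and PROK2 (-1.04 ± 0.30) fell (2 up and 2 down over the list alone; camera adjusted p = 0.555). The 41 interferon response genes had 2 falls, the RNA sensor gene DDX58 (-0.38 ± 0.10) and OAS1 (-0.74 ± 0.21), and 2 over the list alone (camera adjusted p = 0.2). In REF and sham DDX58 averaged 532 ± 104 and 537 ± 86.5, and OAS1 114 ± 48.8 and 152 ± 46.0. With ribosomal RNA as a covariate the calls of DDX58 and OAS1 ended (adjusted p = 0.145 and 0.135), as did those of HMOX1 (0.13) and CXCL8 (0.0508). No gene was called by limma, over all genes or the list alone, among 18 eosinophil and basophil markers, 32 red cell genes, 27 platelet genes, 32 replication-dependent histone genes and 12 MHC class II genes (camera adjusted p = 0.326, 0.899, 0.649, 0.190 and 0.306). Of the 13 mitochondrially encoded genes, 9 fell over the list alone and no gene over all genes by limma. Camera called the list (adjusted p = 4.03e-07, and 0.409 with an estimated correlation). In REF alone against sham, no T cell, NK, monocyte, neutrophil or interferon list member was called by limma. CTSL averaged 392 ± 304 in sham, 451 ± 257 in REF, 900 ± 331 in VHDR and 864 ± 311 in FLASH. In the same order VNN3 averaged 760 ± 176, 680 ± 288, 367 ± 197 and 360 ± 153. NCAM1 (57.9 ± 24.4 in sham, 22.1 ± 15.3 in REF) and PROK2 (55.1 ± 27.8 and 28.9 ± 16.1) were lower in REF as well.

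Each dose rate was then set against sham. At 1 Gy/min the response was mostly upward: 77 genes rose and 2 fell in REF, so that rises were 97.5% of calls, against 83.0% by voom and 80.8% with ribosomal RNA as a covariate. AEN (3.42 ± 0.16), FDXR (3.39 ± 0.16) and DDB2 (2.78 ± 0.13) rose to the highest levels of any group, and CDKN1A rose by 2.45 ± 0.18, from 268 ± 86.8 in sham to 1447 ± 371, above every sham library in 8 of 8. Of the p53 targets 32 rose and no gene fell (39 and 0 over the list alone; camera adjusted p = 1.84e-110, and 1.69e-14 with an estimated correlation), as did 29 of the 35 dose markers. No immediate early gene was called by limma in REF (1 fell over the list alone; camera adjusted p = 9.75e-05, but 0.456 with an estimated correlation). The list median was -0.21. With ribosomal RNA as a covariate the median was -0.13 and 1 member fell by limma. Over 50% ribosomal RNA the median was 0.03 and 0 members fell. A fall in REF, small beside that at the high rates, was not excluded. Within the libraries over 50% ribosomal RNA, 3 REF against 8 sham, 39 genes were called, 33 up, and 22 p53 targets rose.

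At 600 Gy/s, 569 genes rose and 384 fell in VHDR against sham. FDXR rose by 2.74 ± 0.16, DDB2 by 2.26 ± 0.13 and CDKN1A by 1.03 ± 0.18, and 34 p53 targets rose while BTG2 fell (37 and 4 over the list alone; camera adjusted p = 2.09e-42, and 4.34e-10 with an estimated correlation). Immediate early genes fell in 15 of 24 cases, EGR2 by -4.65 ± 0.34, from 748 ± 270.2 in sham to 31.5 ± 17.1, and FOSL1 rose (list median -1.11; camera adjusted p = 6.23e-28, and 0.00135 with an estimated correlation). Hypoxia response genes fell in 10 of 30 cases, with HK2 at -2.07 ± 0.32 and the mitophagy gene BNIP3 at -1.81 ± 0.32 (adjusted p = 0.182 for the list with an estimated correlation). Of the heat shock genes, HSPH1 (0.98 ± 0.23), BAG3 (0.81 ± 0.20) and HSP90AA1 (0.42 ± 0.12), chaperones or their partners, rose, and HERPUD1 fell (-0.51 ± 0.09); 7 rose and 1 fell over the list alone (camera adjusted p = 0.0413; 0.688 with an estimated correlation). Within the libraries over 50% ribosomal RNA, 5 VHDR against 8 sham, 520 genes were called and 14 immediate early genes fell, with a list median of -0.92.

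At 300000 Gy/s, 539 genes rose and 358 fell in FLASH against sham. Rises were 60.1% of calls, against 42.1% by voom, which called 1924, and 64.1% with ribosomal RNA as a covariate. FDXR rose by 2.87 ± 0.16, DDB2 by 2.50 ± 0.13 and CDKN1A by 0.95 ± 0.18, and 36 p53 targets rose while BTG2 fell (40 and 3 over the list alone; camera adjusted p = 3.07e-49, and 8.92e-11 with an estimated correlation). EGR2 fell by -5.16 ± 0.34 and 14 of 24 immediate early genes fell, with 1 rise (list median -1.09; camera adjusted p = 1.87e-34, and 0.000477 with an estimated correlation). Of the mitochondrially encoded genes, 6 fell, among them MT-ND4 (-2.17 ± 0.57), a subunit of complex I, and MT-ATP6 (-2.07 ± 0.53), a subunit of ATP synthase (9 over the list alone; list median -1.68; camera adjusted p = 2.99e-11, but 0.193 with an estimated correlation). FLASH libraries held 17.8% ribosomal RNA against 71.6% in sham, and with that share as a covariate the list median was 0.07, with 0 calls by limma. The same covariate left 577 genes called in FLASH against sham, 438 of them among the 897 called without it and in the same direction. Among those 897, 64 had the opposite sign under the covariate.

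**Figure D3:**
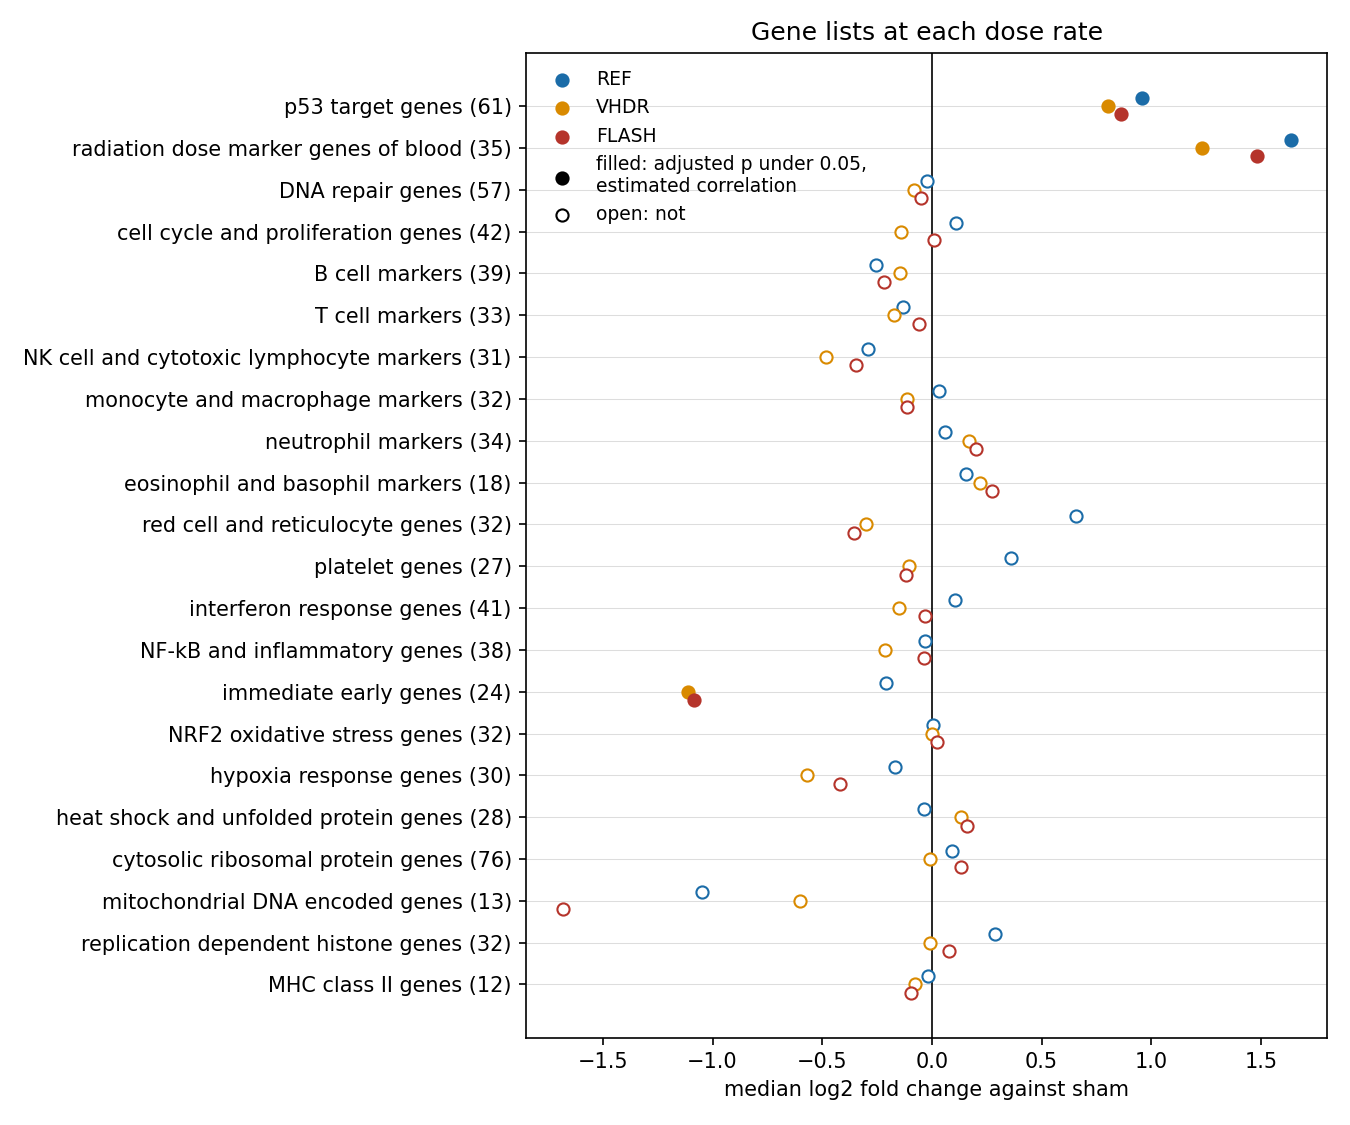
Median log2 fold change against sham of the tested genes in each of the 22 lists (number tested in parentheses), by dose rate, 8 libraries per group. Filled points have a camera adjusted p under 0.05 with an estimated correlation: p53 targets and dose markers at the 3 rates, and immediate early genes in VHDR (-1.11) and FLASH (-1.09) but not REF (-0.21).

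The dose rate groups share the sham libraries, so overlaps were also counted with split controls. REF and VHDR shared 60 rises and REF and FLASH 64, where independent lists of those sizes would share 1.77 and 1.67. Simulated unchanged libraries with the same control shared 0 at most in 20 simulations, but they called almost no gene, so that value says little about a shared control. With 4 sham libraries on each side, so that no control was shared, the overlaps were 46 and 50. VHDR and FLASH shared 420 rises and 182 falls (12.4 and 5.54 for independent lists; 0 simulated; 170 and 50 with split controls).

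The series title asks for effects of dose rate. The comparisons between irradiated groups are made without sham, but they do not isolate the rate. Handling or a processing day shared by the 2 high rates would also set both apart from REF and from sham. The labels give no date or batch to part these readings, for any gene or list. Against REF, EGR2 was lower by -4.39 ± 0.34 in VHDR and -4.90 ± 0.34 in FLASH, with mean normalised values of 672 ± 381 in REF, 31.5 ± 17.1 in VHDR and 20.3 ± 9.44 in FLASH. FOS, EGR1, NR4A1 and OSM fell as well, by -2.32 ± 0.28, -2.30 ± 0.24, -2.24 ± 0.26 and -1.94 ± 0.20 in VHDR and by -2.24, -2.32, -2.55 and -1.89 in FLASH. Each of these genes lay below every REF library in 8 of 8 VHDR and 8 of 8 FLASH libraries. In the other direction SMAD7, which encodes an inhibitor of TGF-beta signalling, rose by 1.21 ± 0.12 in VHDR (adjusted p = 9.11e-08) and 1.27 ± 0.12 in FLASH (adjusted p = 3.85e-08), and CAVIN1, a caveolar coat gene, by 4.43 ± 0.44 and 3.89 ± 0.44. The endosomal GTPase gene RAB7B (3.18 ± 0.33 and 3.19 ± 0.33), EHD4, which acts in endocytic traffic (1.97 ± 0.21 and 1.93 ± 0.21), HMGA1, a chromatin protein gene (1.64 ± 0.17 and 1.45 ± 0.17), and TNFRSF12A, the receptor for TWEAK (2.14 ± 0.24 in both), also rose. All 6 lay above every REF library in 8 of 8 libraries of each high rate. GPR183, an oxysterol receptor gene, fell by -0.91 ± 0.10 and -0.73 ± 0.10 (8 of 8 below every REF library in each), and FAM13A by -1.27 ± 0.18 and -1.51 ± 0.18 (7 of 8 in each).

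**Figure D4:**
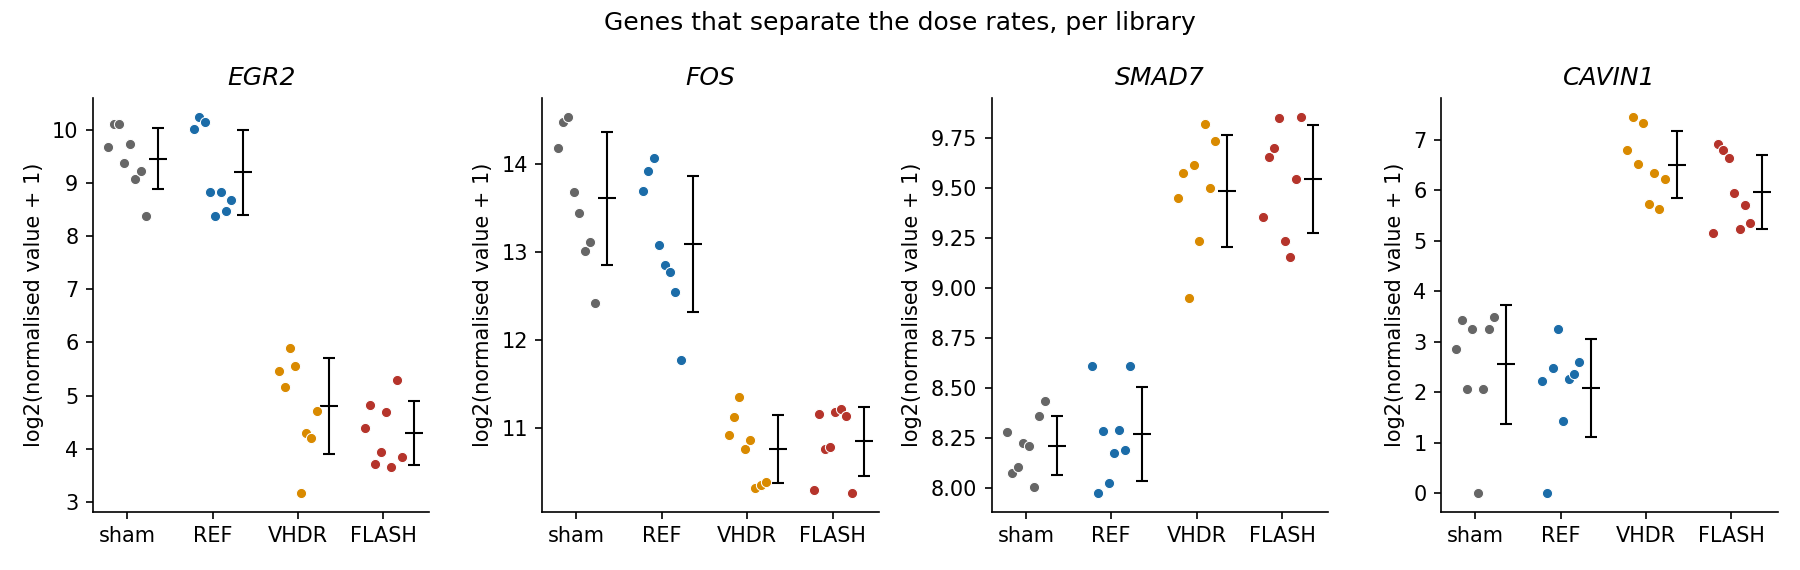
Normalised values of EGR2, FOS, SMAD7 and CAVIN1 on a log2 scale, 1 point per library, with the mean and SD beside each group of 8. EGR2 lies at or above 8.37 in sham and REF and at or below 5.90 in VHDR and FLASH.

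In total 373 genes rose and 230 fell in VHDR against REF, and 264 rose and 113 fell in FLASH against REF. The test of any difference among the 3 rates called 490. The excess of rises depended on scaling: with the total taken without globin, mitochondrial and ribosomal RNA genes, rises went from 61.9% to 40.9% of calls in VHDR and from 70.0% to 49.0% in FLASH. The pair of contrasts shared 223 rises and 94 falls (3.97 and 1.05 for independent lists; 0 simulated; 62 and 21 with 4 REF libraries on each side). Of 24 immediate early genes, 13 fell in each (18 and 16 over the list alone; list medians -0.87 and -0.94; camera adjusted p = 4.77e-22 and 1.22e-33, and 0.00505 and 0.000511 with an estimated correlation). Ribosomal RNA did not separate these groups the way it separated FLASH from sham, so the list was read within each set. Over 50% ribosomal RNA, 5 VHDR against 3 REF libraries, the list median was -0.99 with 9 falls, and under 50% it was -1.01 in VHDR (3 against 5 libraries, 5 falls) and -0.76 in FLASH (7 against 5, 9 falls). For EGR2 the within-set values were -4.34 and -5.01 in VHDR and -4.53 in FLASH, and for SMAD7 1.26, 1.21 and 1.19. With fewer libraries the number of genes called in VHDR against REF was 165 over 50% and 28 under 50%, while FLASH against REF had 422 under 50%, more than the 377 with all libraries.

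As a group, p53 target genes stayed above sham at every rate but were lower at the high rates than at 1 Gy/min. The p53 target score of REF exceeded sham by 1.14 (95% interval 1.05 to 1.24, exact permutation, n = 8), that of VHDR by 0.84 (0.74 to 0.93) and that of FLASH by 0.98 (0.89 to 1.07), each at an adjusted p of 0.000233. The score was lower than in REF by -0.31 in VHDR (-0.40 to -0.22, adjusted p = 0.000233) and by -0.17 in FLASH (-0.25 to -0.09, adjusted p = 0.000559), by exact permutation tests. In VHDR against REF, 10 targets fell and 1, SUSD6 (0.58 ± 0.16), rose (18 and 1 over the list alone; camera adjusted p = 2.91e-08, and 0.00122 with an estimated correlation). CDKN1A fell by -1.42 ± 0.18, MDM2 by -0.65 ± 0.10, FDXR by -0.64 ± 0.16 and DDB2 by -0.52 ± 0.13, and the death receptor gene FAS by -0.89 ± 0.14. In FLASH against REF the 5 that fell were CDKN1A (-1.50 ± 0.18), BTG2 (-1.37 ± 0.20), TP53INP1 (-0.76 ± 0.18), FAS (-0.65 ± 0.14) and MDM2 (-0.53 ± 0.10) (3 rose and 9 fell over the list alone; camera adjusted p = 2.02e-05, and 0.0134 with an estimated correlation). Although FDXR was below every REF library in 8 of 8 FLASH libraries, with -0.51 ± 0.16, it was not called (adjusted p = 0.107). TNFRSF10B was not called in either contrast, with 0.11 ± 0.15 and 0.18 ± 0.15. Within ribosomal RNA sets the score of VHDR minus REF was -0.29 over 50% and -0.28 under 50% (exact permutation adjusted p = 0.0214 for each), and FLASH minus REF was -0.19 under 50% (0.00379 by the same test).

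Members of other lists also differed between the high rates and REF, among them hypoxia, heat shock, histone and red cell genes. None of these 4 lists was called with an estimated correlation. Hypoxia response genes had 6 falls in each contrast, with HK2 (-1.59 ± 0.32 and -1.42 ± 0.32), BNIP3 (-1.68 ± 0.32 and -1.37 ± 0.32), the prolyl hydroxylase gene EGLN1 (-1.25 ± 0.21 and -1.13 ± 0.21) and DDIT4 (-0.94 ± 0.13 and -0.66 ± 0.13). The list was not called with an estimated correlation (adjusted p = 0.382 and 0.447). The chaperone genes HSPH1 (1.27 ± 0.23 and 1.18 ± 0.23), BAG3 (0.98 ± 0.20 and 1.00 ± 0.20) and HSP90AA1 (0.47 ± 0.12 and 0.48 ± 0.12) rose in both, HSPA8 in VHDR (0.40 ± 0.10), and HERPUD1 fell (-0.39 ± 0.09 and -0.37 ± 0.09). The list had an adjusted p of 0.338 and 0.312 with an estimated correlation. The linker histone genes H1-2 (-0.70 ± 0.11 and -0.49 ± 0.11), H1-4 (-0.59 ± 0.11 and -0.60 ± 0.11) and H1-5 (-0.76 ± 0.18 and -0.78 ± 0.18) fell in both contrasts, and H1-3 in VHDR only (-0.75 ± 0.14). They were picked from the histone list after their values were seen. The 32 histone genes as a list had an adjusted p of 0.3 and 0.467 with an estimated correlation. Of the red cell genes SLC25A37, a mitochondrial iron importer, was lower in both (-0.78 ± 0.21 and -0.87 ± 0.21), while the list medians of -0.83 in each had an adjusted p of 0.467 and 0.212 with an estimated correlation. RNU2-6P was also lower than in REF, by -2.50 ± 0.44 and -1.75 ± 0.44.

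The high rates were compared with each other last. No gene was called in FLASH against VHDR by limma (998 at an unadjusted p under 0.05, against 24796 tested; smallest adjusted p 0.419), and voom called 0. EGR2 differed by -0.51 ± 0.34, SMAD7 by 0.06 ± 0.12, CDKN1A by -0.08 ± 0.18 and FDXR by 0.13 ± 0.16. In simulated data for this contrast, 70.4% of genes changed 2-fold with a mean of at least 50 were recovered, and 31.3% of all genes changed 2-fold, so differences of that size could have been missed. The p53 target score was higher in FLASH than in VHDR by 0.14 (95% interval 0.06 to 0.22, exact permutation adjusted p = 0.00311, n = 8), with no single target called by limma. Under 50% ribosomal RNA, with 7 FLASH and 3 VHDR libraries, that difference was 0.09 (exact permutation adjusted p = 0.117). Camera called the p53 list higher (adjusted p = 0.00723), but not with an estimated correlation (adjusted p = 0.193). The mitochondrially encoded genes were lower in FLASH by a list median of -1.08 (camera adjusted p = 6.32e-14; 0.122 with an estimated correlation), beside a ribosomal RNA share of 17.8% in FLASH and 53.8% in VHDR, and with that share as a covariate the median was 0.02.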

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

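Every test of the 3 patterns weighed here was chosen after the pattern had been seen, except the test of a smaller effective dose; the bounds for the splits were also written after the counts had been seen.

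Immediate early genes were lower at both high rates than at 1 Gy/min, and not through ribosomal RNA share or depth alone, since among libraries under 50% ribosomal RNA the list median of FLASH minus REF was still -0.76. Handling or a processing day shared by the 2 high rates stays open: such a cause would set both apart from REF, and 0 genes were called between them by limma (998 at an unadjusted p under 0.05; 0 by voom). The p53 score did differ between them, by 0.14 (exact permutation adjusted p = 0.00311), and camera called that list (adjusted p = 0.00723; 0.193 with an estimated correlation). A differing list had been set as evidence against shared handling, but that bound was wrong, since libraries handled together can still differ by dose rate. A biological effect of dose rate would also set both apart from REF, and the labels give no date or batch that would part the 2 readings.

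Mitochondrial mRNAs were lower in FLASH than in sham. If the ribosomal RNA share moved them, the score should differ with that share inside 1 group, where dose and rate are equal. Within REF it was higher by 2.07 in the 3 libraries over 50% than in the 5 under it (exact permutation p = 0.0179, the smallest possible). Within VHDR the difference was 1.51, with the same exact p. The libraries over 50% were numbers 1, 2 and 4 in REF and 1, 2, 3, 4 and 8 in VHDR. Libraries of the same number in deposit order resembled each other across groups. These tests therefore cannot part the share from whatever the numbers follow, and VHDR is not independent of REF. The fall in FLASH may follow library composition, and no biological explanation was tested.

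p53 targets were lower at both high rates than at 1 Gy/min. Under 50% ribosomal RNA the score of FLASH minus REF was still -0.19, which argues against share or depth. A smaller effective dose at the high rates should lower nearly all responding targets, and 25 of 38 (65.8%, exact 95% interval 48.6 to 80.4) had a lower estimate than REF at both. The bounds written beforehand, over 90% for and under 75% against, would count this against a smaller dose. That reading was left open after the share was seen, because the interval reaches above 75%, and CDKN1A kept 0.420 and 0.389 of its log2 rise in REF while FDXR kept 0.810 and 0.848. The interval treats the 38 genes as independent, although they were measured in the same libraries. The 38 were called on the mean of the 3 rates, which admits genes that rose little in REF. The smallest rises in REF among them were SUSD6 (0.17) and PLK3 (0.20). The share therefore cannot settle the question.

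The libraries were also split at random into groups of the same sizes, 100 times per contrast with the real split included. The real split alone (1 of 100) called as many genes in irradiated against sham (highest other 94), REF against sham (30), VHDR against sham (189), FLASH against sham (1), VHDR against REF (30) and FLASH against REF (8). It was likewise 1 of 100 for any difference among the rates (2). For FLASH against VHDR the real count was 0 by limma, so 100 of 100 splits reach it whatever the data and the count tests nothing.

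In 20 of 256 sets of 8 values, the lowest or highest library lay far from the rest by Dixon's test, where chance alone gives about 1 in 20, or 12.8. In sham the log2 values were CAVIN1 at 0, GADD45A at 6.98 and RPS27L at 7.02. In REF they were ATP6V1G2-DDX39B at 1.57, CARD10 at 4.22, CX3CR1 at 4.0, EHD4 at 6.21, FAM13A at 6.92, MIR210HG at 0, RAB7B at 2.83 and TKT at 10.1. In VHDR they were APOBEC3H at 5.14, ATP6V1G2-DDX39B at 1.83, FCER2 at 0, FDXR at 7.52 and PROK2 at 2.54. In FLASH they were APOBEC3H at 5.09, EDA2R at 7.02, FCER2 at 1.73 and, as a percent, ribosomal RNA at 59.6.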

How the results depend on the processing

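Of the named genes' values under other settings, 661 kept direction and side of the threshold, 74 kept direction but lost the call and 9 reversed. The p53 score kept direction and call with the median, the other pseudocount and the filters, but under 50% ribosomal RNA FLASH minus VHDR lost its call (0.09, exact permutation adjusted p = 0.117). Scaling to the total of all genes called 35 genes in REF, 43 in VHDR and 15706 in FLASH against sham, 13 in VHDR and 33 in FLASH against REF, 1 in FLASH against VHDR and 29 for any rate. It shifts all genes with the ribosomal RNA share. Under it 8 genes turned positive: CD79A 0.24, CD28 0.22, VNN3 0.0469, DDX58 0.53, OAS1 0.17, TKT 0.38, DDIT4 0.27 and HERPUD1 0.54, all below the median of all genes there, 0.84. Voom called 1924 in FLASH against sham, 983 in FLASH against REF and 833 for any rate, and of its calls in FLASH against sham 42.1% were rises (60.1% as reported); the cause was not tested. With no filter, which adds tested genes and refits the intensity trend, irradiated fell to 429 and FLASH to 583, and the cause was not tested. With only the groups compared, irradiated gave 359, from all 32 libraries with the 3 rates pooled as 1 group. The pairs, with fewer libraries, gave 576 for VHDR and 375 for VHDR against REF, but 1136 for FLASH and 413 for FLASH against REF. The other settings were chosen after seeing the data. The ribosomal RNA covariate left 577 in FLASH against sham and turned MS4A1 to -0.13, from 0.02; the cause was not tested. Over 50% ribosomal RNA, fewer libraries gave 39 in REF, 520 in VHDR and 165 in VHDR against REF; under 50%, 28 in VHDR against REF and 204 for any rate. FLASH against sham ranged from 606 without FLASH replicate 3 to 1095 without FLASH replicate 8. Of 66 list calls, an estimated correlation left 16 and fry 28. The B cell score of FLASH minus REF, 0.02, became -0.0105 with the median and -0.0111 with a mean of at least 50, neither called; the cause was not tested. DESeq2, its size factors, sva and a replicate block, all planned, were not run; DESeq2 needs counts, and sva was left out by choice. No paired analysis was made because the labels tie no library to a donor and a number in deposit order does not pair libraries. In 30 of 32 libraries the most similar library of other groups bore the same number in deposit order (4 by chance). In 24 of 32 this held in every other group. With group means and ribosomal RNA share removed, the median correlation was 0.56 for the same number and -0.12 for other numbers. This likeness is strong, but it is a hint from the data, not the design. If donors do recur, the unpaired tests used here could miss small changes, in the B cell score among others. Depth limits calls of low genes: median reads outside ribosomal RNA were 2.93 M in sham and 2.70 M in VHDR, against 15.3 M in REF and 16.6 M in FLASH.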

Other observations

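The tests of wider TGF-beta and sterol responses were set before their lists were read, but after SMAD7, SKIL, PMEPA1 and SQLE had been seen. SKIL and PMEPA1, which TGF-beta signalling induces and which restrain it as SMAD7 does, rose against REF by 0.88 ± 0.12 and 1.96 ± 0.26 in VHDR and by 0.94 and 1.99 in FLASH. Among 26 other TGF-beta response genes, 5 rose in VHDR and 3 in FLASH, and none fell by limma. The largest shift at each rate was nevertheless a fall, of THBS1 (-0.99 ± 0.31 and -1.04 ± 0.31), which limma did not call (adjusted p = 0.0788 and 0.0831). Those called in both were SKI (0.73 ± 0.15 and 0.62 ± 0.15), TGIF1 (0.35 ± 0.10 and 0.45 ± 0.10) and KLF10 (0.84 ± 0.19 and 0.79 ± 0.19), while LDLRAD4 and NEDD9 were called in VHDR only. Camera called the list in both (adjusted p = 2.28e-06 and 4.15e-05, and 2.61e-05 and 0.000122 with an estimated correlation). The median was 0.32 in VHDR (95% interval 0.08 to 0.53) and 0.22 in FLASH (0.12 to 0.43), the lower of them under the 0.3 set for a wide response and above the 0.1 set against it. A wider TGF-beta response may therefore exist at a small size but stays open.

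SQLE, an enzyme of cholesterol synthesis, rose against REF by 1.56 ± 0.21 in VHDR and 1.56 in FLASH. Of 25 other sterol synthesis genes, INSIG1 (1.49 ± 0.21 and 1.34 ± 0.21) and CYP51A1 (0.76 ± 0.15 and 0.98 ± 0.15) rose in both and none fell by limma. The list median was 0.0463 in VHDR (95% interval -0.12 to 0.18) and 0.12 in FLASH (0.05 to 0.26), with camera adjusted p of 0.0930 and 0.00288 (0.134 and 0.0134 with an estimated correlation). The 0.0463 in VHDR, under the 0.1 set against it, argues against a wide rise of sterol synthesis genes at both rates. In FLASH alone, where camera called the list at a median of 0.12, a small rise was not excluded. The need for an interval of the median under 0.3 was added after these values were seen and left both readings as they were.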
